A study of Mus musculus with 18 samples.

How the data were processed

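Polyadenylated RNA from mouse gastrocnemius, the large calf muscle, was sequenced by the study in 18 stranded libraries, 3 in each of 6 groups: flox/flox or Zfp697 muscle knockout (mKO) mice, each kept as controls, unloaded for 10 days, or reloaded for 3 days. Per the labels, the authors aligned reads with STAR 2.7.3a to GRCm38.p6 and counted them with featureCounts 2.0.3, while the file headers name featureCounts 1.6.4 and the release 94 annotation. The deposited table holds raw counts of reads per gene, summed over exons, with no scaling, and its header shows no option for strand, read pairs or reads that map to several places. Values of antisense genes and of genes with close copies, such as the globin, H2 and metallothionein genes, Srp54b and Plet1os, are therefore uncertain. Of 54532 genes, 54409 had a symbol in the reference table of gene names, 32258 had at least 1 count and 17833 were tested after edgeR's default low-count filter. Total counts ran from 45069595 to 51592566 per library, all 18 libraries were used, and a check of library pairs for duplicates found none.

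Counts were scaled by TMM factors and tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on 1 model with 6 group means, 12 residual degrees of freedom and a common dispersion of 0.0197. There were 12 contrasts: 3 between conditions in each genotype, 3 between genotypes within a condition, and 3 interactions, which test whether the change differs between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The standard error of a log2 fold change was derived from the fold change and its F statistic. Expression is given as CPM, the count scaled to a fixed library total, with TMM factors, and log2 CPM for library levels used a prior count of 2. The 35 gene lists were fixed before the data were examined, and were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with adjustment over the lists. Beside that, an estimated correlation and the fry test were run. Where the report describes a called list, the number of members called over all tested genes is given with the number called when adjusted over the list alone. Symbols replaced in the annotation, Cyr61 and Ctgf, were not found under those names.

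The named genes followed a rule fixed before the data were examined. Zfp697 came first in every comparison. For each comparison the 6 largest rises and 6 largest falls were taken among called genes with a mean of at least 1 CPM in a compared group and with CPM ranges that did not overlap between the groups, which chance gives in 10% of genes. Non-overlap was not asked of interactions, and clone or model names were skipped. For each list up to 4 called members were taken by size, and the 2 most abundant members where fewer were called. Where a comparison called fewer than 3 genes, the 5 smallest p were named as not passing.

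The size of the response was compared between genotypes over the genes called in the average of both genotypes. Each gene's log2 change was signed so that the direction of that average counted as positive. The median over genes of the mKO minus flox difference was tested with an exact two-sided permutation test over 400 relabellings. The alternatives were RLE size factors, total counts, no low-count filter, a stricter filter of 1 CPM in 3 libraries, a block for replicate number, a model of only the compared groups, DESeq2 1.42.0 with its Wald test, and leaving out each library in turn. On simulated counts with 3 libraries per group the edgeR test recovered 92% of 2-fold changes in a contrast between groups and 66% in an interaction. The changed genes all had a mean of at least 1 CPM. Among genes without a simulated change, edgeR called 5 in that contrast and 13 in the interaction, and DESeq2 called 22 and 28. The authors also deposited 4 DESeq2 tables, of which the log2 fold changes and standard errors are in log2 units and the other columns hold p-values and adjusted p-values. They were compared with the counts but were not used for any call. The labels do not say that the 3 libraries of a group come from separate animals, so the p-values measure only the spread between these samples.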

Results

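The study measured gene expression in the gastrocnemius of female C57BL/6 mice with an intact Zfp697 gene (flox/flox) or, by the labels, with the gene deleted in skeletal muscle (mKO). Hindlimb unloading removes body weight from the calf muscles, and reloading returns it. The 6 groups held 3 libraries each, with total counts of 45069595 to 51592566 and 22341 to 23418 genes with a count per library. Values below are log2 fold changes with their standard error (SE), unless CPM is named. The SE comes from the fit of all 18 libraries, 3 per group, which shares its estimate of the spread across the groups. The first principal component held 30.3% of the variance and placed flox reloading at 57.4 ± 9.1 (SD, n = 3), mKO reloading at 22.2 ± 10.9, and the other 4 groups between -32.8 and -6.3.

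Zfp697, the targeted zinc finger gene, was measured to see how its expression followed loading and genotype. In flox muscle its level was 1.19 ± 0.35 CPM (SD, n = 3) at control, 1.65 ± 0.081 CPM at unloading and 2.57 ± 0.23 CPM at reloading. It rose from control to reloading by 1.1 ± 0.26 log2 (adjusted p = 0.00429). In libraries labelled mKO it stood at 1.2 ± 0.13 CPM at control, 1.66 ± 0.72 CPM at unloading and 1.68 ± 0.25 CPM at reloading. The mKO minus flox difference at reloading, -0.61 ± 0.25 log2, did not pass (adjusted p = 0.172). Zfp697 (ENSMUSG00000050064) lies on chromosome 3 from 98382461 to 98753812 on the plus strand of GRCm38. Its counts of 45 to 137 per library were summed over the whole gene, while the deleted part is not stated and other cell types keep the gene, so these values do not test the genotype labels.

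**Figure D1:**
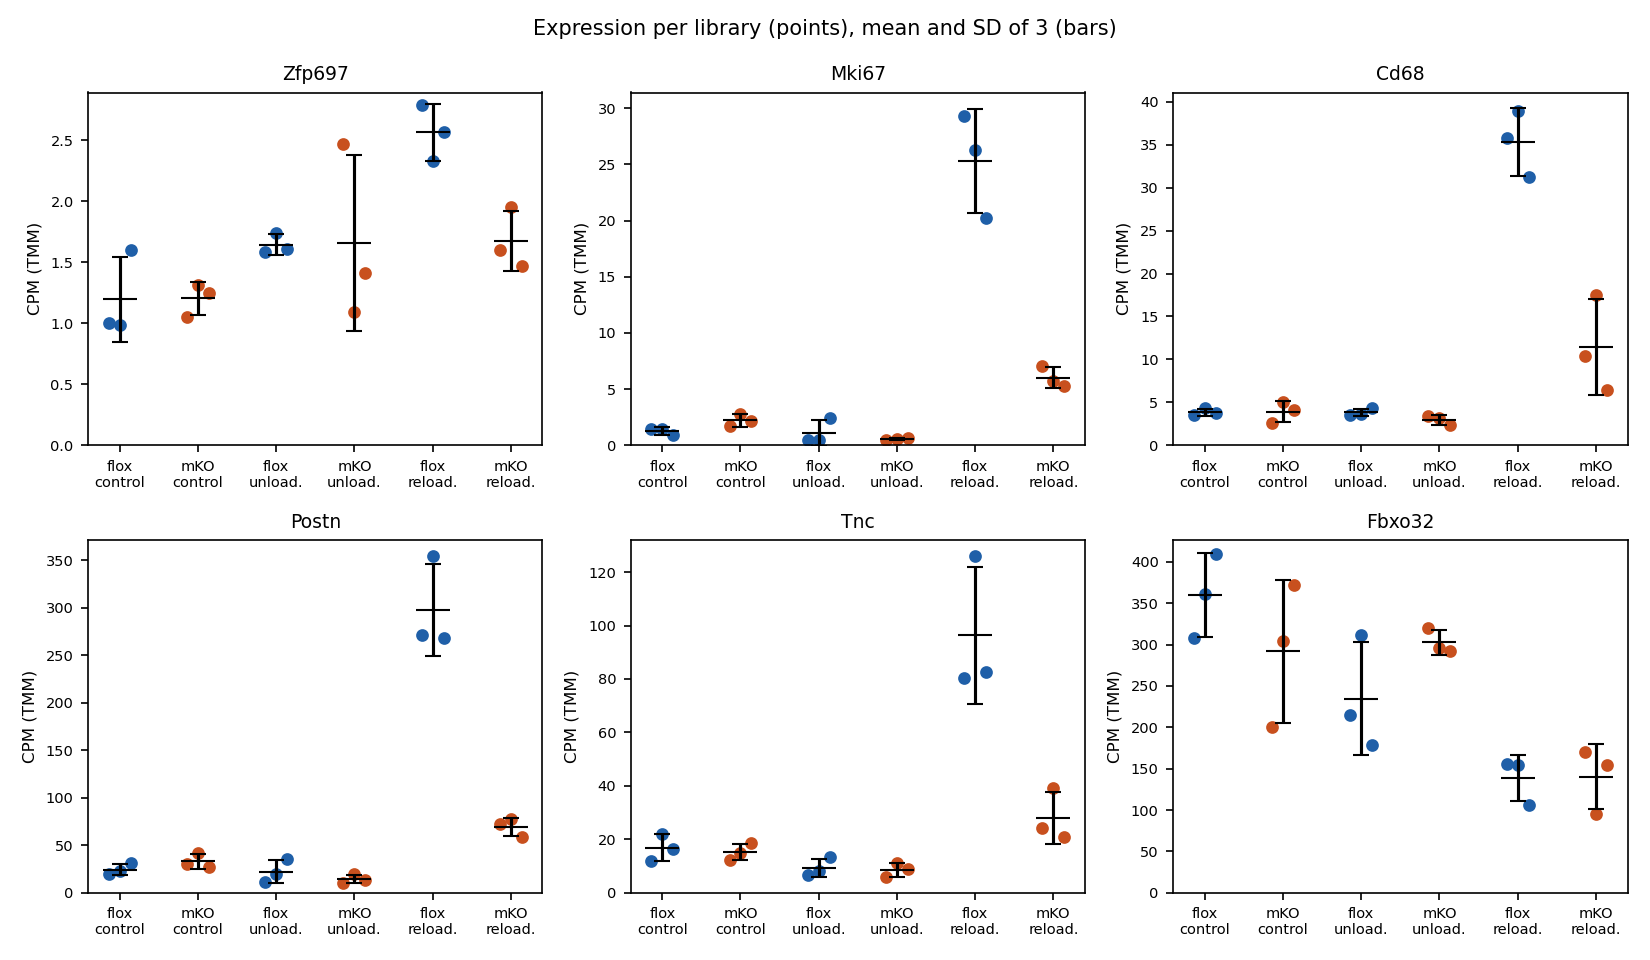
CPM with TMM factors for Zfp697, Mki67, Cd68, Postn, Tnc and Fbxo32 in each library (points), with the mean and SD of 3 libraries (bars), by genotype and condition. Cd68 stood at 35.4 ± 3.93 CPM in flox reloading and 11.4 ± 5.6 CPM in mKO reloading.

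Unloading against control in flox muscle asked what disuse changes when Zfp697 is intact. Of 32 extracellular matrix genes 12 fell and 0 rose (19 fell when adjusted over the list alone). Among them were the collagen genes Col1a1 at -1.97 ± 0.31, Col1a2 at -1.59 ± 0.24 and Col6a2 at -1.27 ± 0.18. The list median was -0.67 (adjusted p = 2.52e-16; adjusted p = 0.285 with an estimated correlation). Of 46 nuclear oxidative phosphorylation genes 9 fell (17 adjusted over the list alone). Examples were Sdhb, a subunit of succinate dehydrogenase, at -0.58 ± 0.1, and Atp5g3, a subunit of ATP synthase, at -0.49 ± 0.09. That list had a median of -0.27 (adjusted p = 6.93e-12; adjusted p = 0.344 with an estimated correlation). Of 20 atrophy and FoxO target genes 4 rose (5 adjusted over the list alone), among them Map1lc3a, an autophagosome protein, by 0.79 ± 0.09 and Mt1, a metallothionein, by 1.09 ± 0.23. The list median was 0.15 (adjusted p = 0.000104; adjusted p = 0.0954 with an estimated correlation). The 4 called genes were Mt1, Cdkn1a, Map1lc3a and Bnip3, and the ubiquitin ligase gene Fbxo32 of the same list was not called.

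Single genes with large changes in flox unloading were Slc2a3, a glucose transporter, at 1.91 ± 0.17, Fkbp5, a glucocorticoid-responsive chaperone, at 2.19 ± 0.29, Lcn2 at 2.65 ± 0.46, Mss51 at 2.25 ± 0.32 and Pnmt at 2.52 ± 0.33. Mycn fell by 2.3 ± 0.28 and Lgr6 by 2.31 ± 0.4 on the log2 scale. Fibro-adipogenic progenitor markers had a median of -0.35 (adjusted p = 1.53e-07; adjusted p = 0.285 with an estimated correlation). Of these 4 of 13 fell (7 adjusted over the list alone), including Cd248 at -1.2 ± 0.17 and Cd34 at -0.42 ± 0.07. Tendon markers had a median of -0.83 (adjusted p = 6.12e-05; adjusted p = 0.344 with an estimated correlation), and 3 of 10 fell (6 adjusted over the list alone). Schwann cell markers had a median of 0.54 (adjusted p = 0.000104; adjusted p = 0.421 with an estimated correlation), and 1 of 11 rose (7 adjusted over the list alone). The neutrophil list had a median of 1.67 (adjusted p = 0.0258; adjusted p = 0.46 with an estimated correlation), and 1 of 8 rose (1 adjusted over the list alone). Its level was 2.42 in flox unloading replicate 3 against 0.14 and 0.05 in the other 2 libraries. Without that library the median was -0.7 (adjusted p = 0.739). In all, 1024 of 17833 genes changed, 477 up and 547 down. Of 54 named genes 22 passed without each single library, and of 13 called lists 10. The count was 364 without flox unloading replicate 1, 655 without its replicate 3, 434 without flox control replicate 1 and 416 without its replicate 2. It was 1651 with no low-count filter and 1538 with DESeq2.

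The same comparison in mKO muscle gave 1382 changed genes, 729 up and 653 down. Of 65 named genes 28 passed without each single library, and of 17 called lists 10. Of 32 matrix genes 18 fell and 0 rose (25 fell adjusted over the list alone), among them Col1a1 at -2.24 ± 0.31, Col3a1 at -1.79 ± 0.26 and Sparc, a collagen-binding protein, at -1.41 ± 0.14. The list median was -0.93 (adjusted p = 9.72e-28; adjusted p = 0.0692 with an estimated correlation). Interferon response genes fell, 8 of 31 (19 adjusted over the list alone), with Ifi44 at -1.52 ± 0.28, Ifit3 at -1 ± 0.2 and Rtp4 at -0.76 ± 0.16. Their median was -0.45 (adjusted p = 2.28e-10; adjusted p = 0.0692 with an estimated correlation). The atrophy list rose with a median of 0.25 (adjusted p = 4.02e-07) and this held with an estimated correlation (adjusted p = 0.0156). Its Map1lc3a rose by 0.72 ± 0.09, and 6 of its 20 genes were called (9 adjusted over the list alone). Lcn2 rose by 2.44 ± 0.45 and Fkbp5 by 2.13 ± 0.29, while Clec11a fell by 2.44 ± 0.28 on the log2 scale.

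Between the genotypes, 295 genes rose in both unloading comparisons against 19.5 under independence, 277 fell in both against 20, and 0 were called in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at 0.434. Over 3394 genes the median of the mKO minus flox differences in response size was 0.023 log2 (exact permutation p = 0.58, two-sided). Its sign turned without flox control replicate 3 (-0.007) and without flox unloading replicate 2 (-0.01). The mKO count was 508 and 596 without mKO unloading replicates 1 and 3, 822, 731 and 722 without mKO control replicates 1, 2 and 3, and 879 when only those 2 groups were modelled.

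Reloading against unloading in flox muscle asked what follows when weight returns. Proliferation genes rose: of 31 cell cycle genes 29 rose and 0 fell (30 adjusted over the list alone), with a median of 2.56. Examples were the mitotic genes Cenpf at 5.34 ± 0.5 and Ccnb2 at 4.86 ± 0.52, and the topoisomerase Top2a at 4.67 ± 0.41. Mki67, a proliferation marker, stood at 1.11 ± 1.15 CPM (SD, n = 3) in flox unloading and at 25.3 ± 4.63 CPM in flox reloading. Of 32 matrix genes 28 rose and 1 fell (28 and 1 adjusted over the list alone). Examples were Timp1, a protease inhibitor, at 4.06 ± 0.33, Postn at 3.76 ± 0.32, Tnc at 3.36 ± 0.31 and Col3a1 at 3.05 ± 0.27. Macrophage and monocyte markers rose in 21 of 26 cases with 1 down (22 and 1 adjusted over the list alone). Examples were Cx3cr1, a chemokine receptor, at 3.46 ± 0.4 and Cd68, a lysosomal macrophage marker, at 3.2 ± 0.28. The adjusted p was 5.57e-36 for the cell cycle list, 5.57e-36 for the matrix list and 2.13e-14 for the macrophage list. With an estimated correlation they were adjusted p = 0.013, adjusted p = 0.0272 and adjusted p = 0.137.

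Interferon response genes rose in 24 of 31 cases (27 adjusted over the list alone) in flox reloading, with Cxcl10 at 2.58 ± 0.46 and Isg15 at 2.1 ± 0.27. Their list had a median of 0.74 (adjusted p = 3.04e-12; adjusted p = 0.0272 with an estimated correlation). The atrophy and FoxO list fell with a median of -0.4 (adjusted p = 3.06e-05; adjusted p = 0.0272 with an estimated correlation). Of its 20 genes 10 fell and 2 rose (12 and 3 adjusted over the list alone). Klf15, a glucocorticoid-responsive transcription factor, fell by 1.33 ± 0.1 and Map1lc3a by 1.09 ± 0.09 on the log2 scale, while Mt2, a metal-binding protein, rose by 1.99 ± 0.38. Sarcomere strain and repair genes rose in 13 of 14 cases (13 adjusted over the list alone), with Ankrd1 at 3.26 ± 0.39 and Csrp3 at 2.81 ± 0.62. The strain list had a median of 1.97 (adjusted p = 3.5e-10; adjusted p = 0.121 with an estimated correlation). Regeneration genes such as Mymk, the myoblast fusion protein, at 4.06 ± 0.48 and Myh3, embryonic myosin, at 2.63 ± 0.44 also rose. Of 15 genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), and the list had a median of 0.8 (adjusted p = 0.00631; adjusted p = 0.144 with an estimated correlation). The neuromuscular junction and denervation list had a median of 0.33 (adjusted p = 0.00825; adjusted p = 0.0535 with an estimated correlation). Of its 14 genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). Heat shock genes rose in 7 of 10 cases (8 adjusted over the list alone), with Hspb1 at 2.19 ± 0.28. The heat shock median was 1.01 (adjusted p = 4.31e-07; adjusted p = 0.0976 with an estimated correlation).

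The cytokine, chemokine and NF-kB list rose in 23 of 31 cases (23 adjusted over the list alone), with Il6 at 2.89 ± 0.69 and Ccl8 at 2.7 ± 0.5. This list had a median of 1 (adjusted p = 1.35e-07; adjusted p = 0.0535 with an estimated correlation). Glycolysis and glycogen genes fell in 9 of 19 cases with 1 up (9 adjusted over the list alone), with Phka1, a phosphorylase kinase subunit, at -1.21 ± 0.12. The glycolysis median was -0.21 (adjusted p = 9.09e-05; adjusted p = 0.276 with an estimated correlation). In the unfolded protein response list, Chac1, a glutathione-degrading enzyme, fell by 4.38 ± 0.54 on the log2 scale while Sdf2l1 rose by 1.7 ± 0.19. That list had a median of 0.41 (adjusted p = 0.0299; adjusted p = 0.364 with an estimated correlation). Of its 17 genes 9 rose and 3 fell (10 and 3 adjusted over the list alone). It was not called without flox unloading replicate 2 (adjusted p = 0.0507) or without flox reloading replicate 1 (adjusted p = 0.0584). In all, 5692 genes changed, 3032 up and 2660 down. Of 129 named genes 109 passed without each single library, and of 22 called lists 17. Flox reloading libraries had TMM factors of 1.08 ± 0.016 (SD, n = 3) against 0.975 to 1 in the other groups. Scaling by total counts instead shifted the median of all genes by 0.109 log2, so that 71.8% of the called genes were higher against 53.3%.

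In mKO muscle, reloading against unloading called 3270 genes, 1699 up and 1571 down. Of 114 named genes 68 passed without each single library, and of 14 called lists 9. Cell cycle genes rose in 22 of 31 cases with 1 down (25 adjusted over the list alone), with Bub1 at 3.95 ± 0.73, Mki67 at 3.49 ± 0.46 and Cdk1 at 3.28 ± 0.57. Mki67 and Cdk1 had been lower at unloading than at control in mKO, at -2.04 ± 0.48 and -2.12 ± 0.61. Their rise thus started from a lowered level. The cell cycle median was 1.19 (adjusted p = 4.47e-16; adjusted p = 0.0831 with an estimated correlation). Matrix genes rose in 22 of 32 cases with 1 down (25 adjusted over the list alone), with Timp1 at 3.04 ± 0.34 and Col1a1 at 2.51 ± 0.32. The matrix median was 1.26 (adjusted p = 2.97e-29; adjusted p = 0.0831 with an estimated correlation). The atrophy and FoxO list fell with a median of -0.55 (adjusted p = 4.31e-11; adjusted p = 0.00171 with an estimated correlation). Of its 20 genes 12 fell and 0 rose (13 fell adjusted over the list alone), among them the ubiquitin ligase Fbxo32 at -1.11 ± 0.24 and Klf15 at -0.91 ± 0.1. Macrophage markers rose in 6 of 26 cases with 1 down (8 adjusted over the list alone), with Cd68 at 1.94 ± 0.28. The macrophage median was 0.43 (adjusted p = 0.00202; adjusted p = 0.66 with an estimated correlation). The adjusted p of that list was 0.0558 without mKO unloading replicate 3 and 0.0528 without mKO reloading replicate 2. Interferon genes had a median of 0.42 (adjusted p = 2.37e-08; adjusted p = 0.091 with an estimated correlation). Of 31 genes 12 rose (18 adjusted over the list alone), with Oasl2 at 1.25 ± 0.2. Between the genotypes 1271 genes rose in both comparisons against 289 under independence and 1242 fell in both against 234. The 4 genes called in opposite directions, named here after their values were seen, were Il1b (2.73 in flox, -3.44 in mKO), Dmac2 (-0.29 and 0.22), Tmem136 (-0.43 and 0.48) and Gal3st1 (-1.21 and 1.16). The interaction for this change called 0 genes, so none of the 4 passed that test of the difference. The mKO count was 2058 and 2107 without mKO unloading replicates 1 and 3, and 2107 when only those 2 groups were modelled.

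Reloading against control asked how far each genotype stood from its starting state. In flox muscle the cell cycle list was higher by a median of 2.44 (adjusted p = 1.28e-49; adjusted p = 0.00411 with an estimated correlation). Of its 31 genes 30 were higher (30 adjusted over the list alone), such as Ccnb1 at 4.69 ± 0.51 and Mki67 at 4.31 ± 0.42. The neuromuscular junction and denervation list was higher by a median of 0.74 (adjusted p = 4.62e-06; adjusted p = 0.00411 with an estimated correlation). Of 14 genes 8 were higher and 1 lower (8 and 1 adjusted over the list alone), among them the fetal acetylcholine receptor subunit Chrng at 2.76 ± 0.57. Macrophage markers were higher in 22 of 26 cases (24 adjusted over the list alone) with Cd68 at 3.2 ± 0.28. Their median was 1.26 (adjusted p = 1.54e-20; adjusted p = 0.0738 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower in 26 of 46 cases (34 adjusted over the list alone), with Cox8b at -0.82 ± 0.09. Their median was -0.32 (adjusted p = 4.18e-11; adjusted p = 0.251 with an estimated correlation). The atrophy list had a median of -0.22, a mean of 0.02 and a test result of lower (adjusted p = 0.0222; adjusted p = 0.181 with an estimated correlation). Of its 20 genes 9 were lower and 3 higher (10 and 3 adjusted over the list alone). The call was lost without flox reloading replicate 3 (adjusted p = 0.147). Fbxo32 was lower at -1.38 ± 0.24, while the metallothionein genes Mt1 and Mt2 were higher by 2.05 ± 0.23 and 3.38 ± 0.43. In all, 4035 genes differed in flox, 2193 up and 1842 down. Of 120 named genes 92 passed without each single library, and of 21 called lists 17. Scaling by total counts shifted the median of all genes by 0.146 log2 and left 80.5% of called genes higher, against 54.3%.

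In mKO muscle 389 genes differed between reloading and control, 239 up and 150 down. Without each single library 11 of 37 named genes passed, and 7 of 15 called lists. In the neuromuscular junction and denervation list 3 of 14 genes were higher and 1 lower (9 and 1 adjusted over the list alone). The higher ones were Chrng at 4.07 ± 0.73, Chrnb1 at 0.84 ± 0.14 and Myog at 1.14 ± 0.27. Myog is also on the regeneration list. Gadd45a was lower at -0.52 ± 0.11. The denervation median was 0.45 (adjusted p = 3.43e-07; adjusted p = 0.00255 with an estimated correlation). Sarcomere strain genes were higher in 10 of 14 cases (13 adjusted over the list alone), with Ankrd1 at 2.33 ± 0.38. The strain median was 1.38 (adjusted p = 1.93e-17; adjusted p = 0.0607 with an estimated correlation). Cell cycle genes had a median of 0.74 (adjusted p = 1.15e-11; adjusted p = 0.142 with an estimated correlation). Of 31 genes 3 were higher (15 adjusted over the list alone). Both genotypes shared 190 higher genes against 29.4 under independence and 135 lower genes against 15.5, and 0 were called in opposite directions. The mKO count was 85 without mKO reloading replicate 2, 143, 156 and 125 without mKO control replicates 1, 2 and 3, 138 when only those 2 groups were modelled, 1216 with no low-count filter and 891 with DESeq2.

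The comparison of mKO with flox at control and at unloading asked whether the genotype groups differed before reloading. At control edgeR called 0 genes, with 718 at an unadjusted p under 0.05 and 0 by DESeq2. Aff3 (-0.9 ± 0.19) and Rnf114 (-0.33 ± 0.07) had the smallest p without passing (adjusted p = 1). At unloading it called 0 genes, with 816 at an unadjusted p under 0.05 and 0 by DESeq2. Here the ubiquitin ligase gene Trim63 (0.35 ± 0.08) and Gng2 (-0.57 ± 0.12) were among the smallest p without passing (adjusted p = 1). With no low-count filter the counts were 148 at control and 133 at unloading. Of 4 lists called at control 1 passed without each single library, and of 8 at unloading 2. Of the lists, interferon response had a median of 0.16 in mKO minus flox at control (adjusted p = 9.55e-05; adjusted p = 0.933 with an estimated correlation). Of its 31 members 0 were called (0 adjusted over the list alone), with 0.09 ± 0.11 for Ifi27 and 0.16 ± 0.11 for Irgm1. At unloading the Schwann cell list had a median of -0.46 (adjusted p = 4.13e-10; adjusted p = 0.755 with an estimated correlation). Of its 11 members 0 were called (0 adjusted over the list alone). Pmp22 gave -0.46 ± 0.17. The complement list had a median of -0.18 there (adjusted p = 8.87e-05; adjusted p = 0.755 with an estimated correlation), with 0 of 13 called (0 adjusted over the list alone).

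The comparison of mKO with flox at reloading asked whether muscle labelled mKO regrows with a different expression profile. It called 875 genes, 189 higher and 686 lower in mKO. Cell cycle genes were lower in 27 of 31 cases and higher in 0 (30 lower adjusted over the list alone), with a median of -1.51. Among them were the cyclin Ccnb1 (ENSMUSG00000041431) at -2.83 ± 0.43, Cenpf at -2.34 ± 0.39 and Top2a at -2.26 ± 0.35. Mki67 stood at 6.02 ± 0.921 CPM (SD, n = 3) in mKO and 25.3 ± 4.63 CPM in flox reloading, against 2.2 ± 0.576 and 1.27 ± 0.321 CPM at control. Macrophage and monocyte markers were lower in 19 of 26 cases (24 adjusted over the list alone), with a median of -1.19. Examples were Cd68 (ENSMUSG00000018774) at -1.63 ± 0.26 and the complement genes C1qa at -1.17 ± 0.18 and C1qb at -1.22 ± 0.19. Matrix genes were lower in 8 of 32 cases (23 adjusted over the list alone), with a median of -0.52. Examples were Postn (ENSMUSG00000027750) at -2.1 ± 0.3, Tnc at -1.78 ± 0.29, the collagen crosslinking enzyme Lox at -1.53 ± 0.22 and Ccn2 at -1.5 ± 0.26. The adjusted p was 2.41e-46 for the cell cycle list, 1.94e-35 for the macrophage list and 5.42e-17 for the matrix list. With an estimated correlation they were adjusted p = 0.0047, adjusted p = 0.0262 and adjusted p = 0.097. Without any 1 library the adjusted p of the cell cycle and macrophage lists at the preset correlation stayed at or below 1.29e-30. The estimated correlation was not run without single libraries. Cytokine and chemokine genes were lower in 10 of 31 cases (15 adjusted over the list alone), with a median of -0.41 (adjusted p = 8.26e-11; adjusted p = 0.0262 with an estimated correlation). Antigen presentation genes were lower in 4 of 17 cases (12 adjusted over the list alone), with a median of -0.46 (adjusted p = 3.29e-09; adjusted p = 0.0483 with an estimated correlation).

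**Figure D2:**
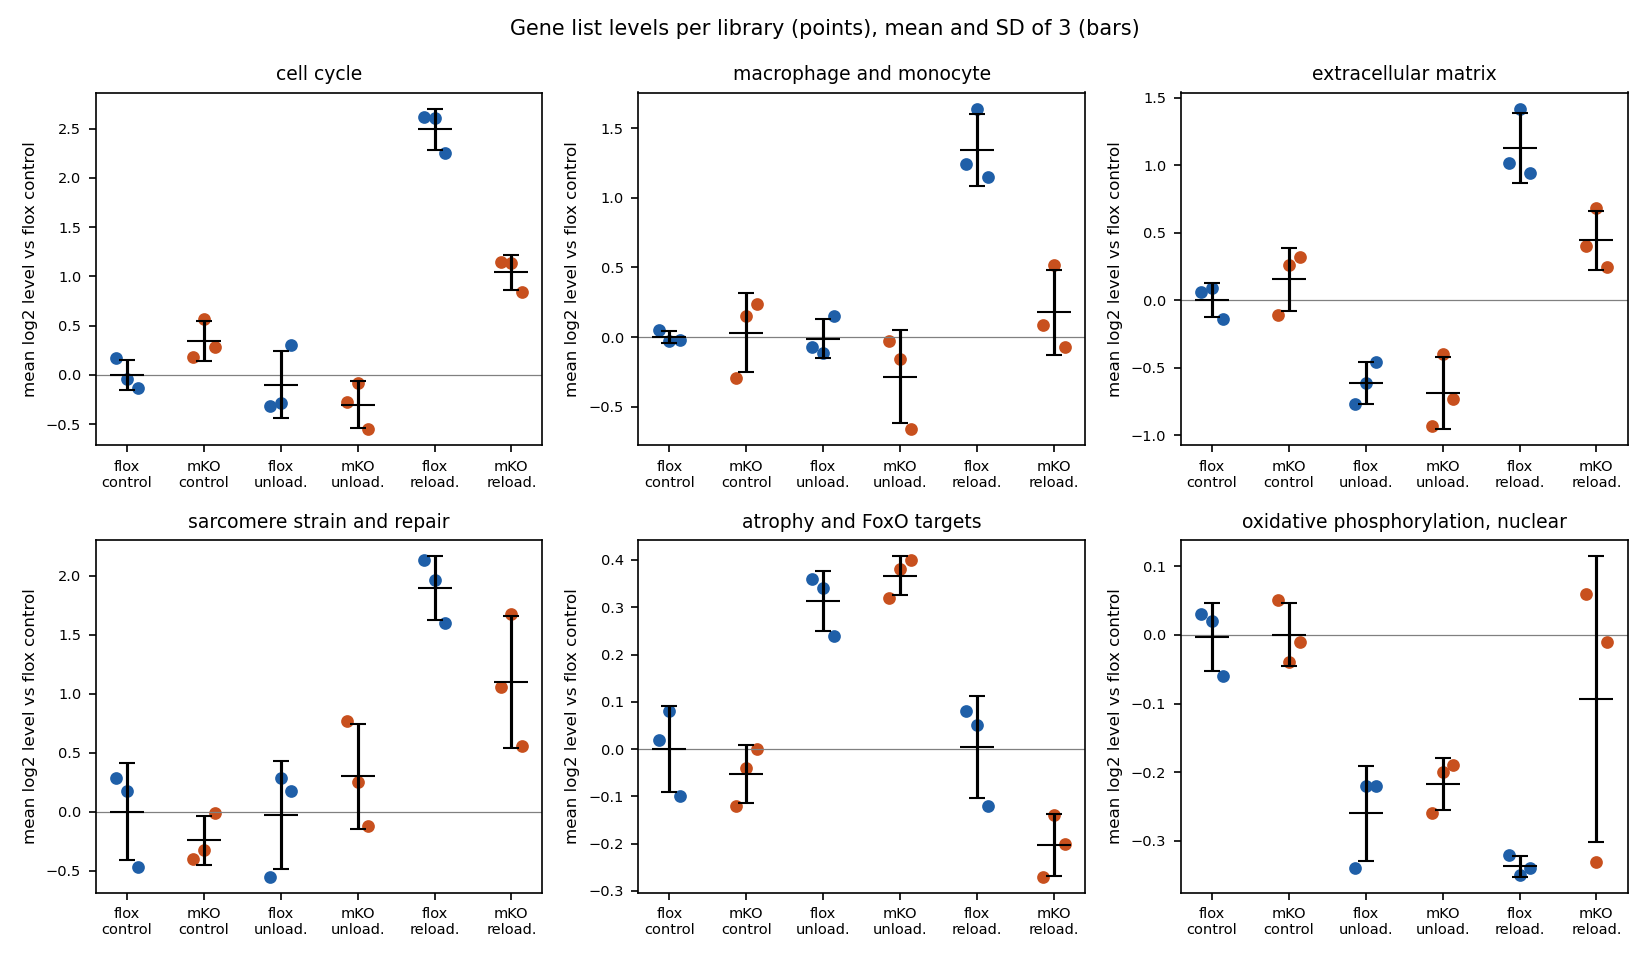
Mean log2 level of 6 gene lists in each library relative to the flox control mean (points), with the mean and SD of 3 libraries (bars), by genotype and condition. The cell cycle list stood at 2.25 to 2.62 in flox reloading and at 0.84 to 1.15 in mKO reloading.

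Muscle and nerve-related genes also differed at reloading. The neuromuscular junction and denervation list had a median of -0.22 (adjusted p = 0.0117; adjusted p = 0.0714 with an estimated correlation). Of 14 genes 3 were lower (4 lower and 1 higher adjusted over the list alone). The sarcomere strain and repair list had a median of -0.68 (adjusted p = 4.55e-06; adjusted p = 0.184 with an estimated correlation). Of 14 genes 4 were lower (5 adjusted over the list alone). The nuclear oxidative phosphorylation list had a median of 0.26 (adjusted p = 4.29e-14; adjusted p = 0.183 with an estimated correlation), with 2 of 46 genes higher (25 adjusted over the list alone). Of 28 TCA cycle and fatty acid oxidation genes 2 were higher (14 adjusted over the list alone), and the list median was 0.31 (adjusted p = 6.29e-10; adjusted p = 0.184 with an estimated correlation). Of 19 glycolysis and glycogen genes 3 were higher (12 adjusted over the list alone), and the list median was 0.26 (adjusted p = 9.39e-09; adjusted p = 0.107 with an estimated correlation). Of 13 fast fibre genes 2 were higher (5 adjusted over the list alone), and the list median was 0.3 (adjusted p = 2e-06; adjusted p = 0.107 with an estimated correlation). Scaling by total counts shifted the median of all genes by -0.134 log2 in this comparison, so the size of these higher medians depends on the scaling. The ribosomal gene Rpl3 was lower at -0.77 ± 0.12 and the lysosomal protease gene Lgmn at -0.77 ± 0.13. Of 14 endothelial markers 2 were lower (7 adjusted over the list alone). Their median was -0.24 (adjusted p = 0.000707; adjusted p = 0.0714 with an estimated correlation), with Pecam1 at -0.48 ± 0.07.

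The mKO reloading libraries did not stand together at reloading. Replicate 2 had a macrophage list level of 0.52 against 0.09 and -0.07 in replicates 1 and 3, a matrix level of 0.68 against 0.4 and 0.25, and an oxidative phosphorylation level of -0.33 against 0.06 and -0.01. The count of 875 genes became 1630 without mKO reloading replicate 2, 364 and 127 without its replicates 1 and 3, and 521 and 185 without flox reloading replicates 1 and 2. It was 1485 with total counts, which shifted the median of all genes by -0.134 log2, 1557 with no low-count filter, 443 when only those 2 groups were modelled and 1387 with DESeq2. Of the 19 called lists 16 passed without each single library. Of the 76 named genes 18 did, among them Ccnb1, Cenpf, Top2a, Cd68, C1qa, C1qb, Postn, Tnc, Lox, Ccn2, Pecam1, Lgmn and Rpl3.

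The interactions tested whether the change itself differed between the genotypes. From control to reloading, cell cycle genes rose less in mKO by a median of -1.72 (adjusted p = 3e-44; adjusted p = 0.00602 with an estimated correlation). Of 31 genes 12 were called (30 adjusted over the list alone), among them Cenpf at -3.73 ± 0.65, Ccnb1 at -3.67 ± 0.73, Mki67 at -2.86 ± 0.55 and Top2a at -2.76 ± 0.53. Macrophage markers differed by a median of -1.15 (adjusted p = 1.01e-26; adjusted p = 0.0485 with an estimated correlation). Of 26 markers 4 were called (22 adjusted over the list alone), including the protease Ctss at -1.59 ± 0.3 and the mannose receptor Mrc1 at -1.01 ± 0.2. Matrix genes differed by a median of -0.67 (adjusted p = 3.63e-20; adjusted p = 0.0967 with an estimated correlation). Of 32 genes 3 were called (19 adjusted over the list alone), including Postn at -2.54 ± 0.42 and Col5a2 at -1.25 ± 0.24. Interferon response genes differed by a median of -0.5 (adjusted p = 4.27e-13; adjusted p = 0.04 with an estimated correlation). Of 31 genes 1 was called (14 adjusted over the list alone), Isg15 at -1.83 ± 0.37. The mKO minus flox differences at reloading alone were smaller, at -2.34 ± 0.39 for Cenpf, -2.83 ± 0.43 for Ccnb1 and -2.26 ± 0.35 for Top2a. They were -2.1 ± 0.3 for Postn and -1.04 ± 0.25 for Isg15. The rest of these interaction values came from levels at control, where edgeR called no gene between the genotypes. In all, 93 genes were called, 4 up and 89 down. Of 23 named genes 0 passed without each single library, and of 19 called lists 13. The count was 12, 6 and 8 without flox control replicates 1, 2 and 3, and 7 and 9 without mKO control replicates 2 and 3. It was 0 and 5 without flox reloading replicates 1 and 2, 6 and 4 without mKO reloading replicates 1 and 3, and 448 without mKO reloading replicate 2. It was 284 with total counts, which shifted the median of all genes by -0.137 log2, 755 with no low-count filter, 158 with the stricter filter, 143 with a replicate block and 422 with DESeq2.

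From unloading to reloading the interaction called 0 genes with edgeR, with 1873 at an unadjusted p under 0.05 and 142 by DESeq2. The smallest p belonged to Carhsp1 (-0.71 ± 0.11), the cytokinesis gene Anln (-1.27 ± 0.23), the prostaglandin synthase Ptgs2 (-3.68 ± 0.66), Incenp (-1.1 ± 0.2) and Lbh (-0.82 ± 0.15), which did not pass (adjusted p = 0.0671). Ptgs2 stood at 4.18 ± 2.09 CPM (SD, n = 3) in flox reloading and at 0.668 ± 0.276 CPM in mKO reloading, against 0.349 ± 0.141 and 0.724 ± 0.376 CPM at unloading. The cell cycle list differed by a median of -1.15 (adjusted p = 1.95e-21; adjusted p = 0.0423 with an estimated correlation), with 0 of 31 called (20 adjusted over the list alone). The cytokine list differed by -0.52 (adjusted p = 1.35e-10; adjusted p = 0.0423 with an estimated correlation) with 0 of 31 called (7 adjusted over the list alone). The immediate early list differed by a median of -1.04 (adjusted p = 9.45e-11; adjusted p = 0.0881 with an estimated correlation), with 0 of 17 called (7 adjusted over the list alone). Its most abundant members, Jun and Nr4a1, differed by -1.08 ± 0.33 and -0.45 ± 0.35. At unloading alone Jun and Nr4a1 stood at 0.5 ± 0.23 and 0.28 ± 0.25 in mKO minus flox, so that level carried part of the difference. From control to reloading they differed by -0.2 ± 0.33 and -0.1 ± 0.35, with -0.38 ± 0.23 and -0.07 ± 0.25 at control. Other members, Egr3, Egr2 and Ccn1, were called lower in mKO at reloading itself. The count was 98 without mKO reloading replicate 2, 3 without mKO unloading replicate 3, 564 with no low-count filter and 10 with a replicate block. Over 7171 genes the median change in the direction of the average was 0.509 log2 in flox and 0.377 in mKO. The median of the mKO minus flox differences gene by gene was -0.127 (exact permutation p = 0.115, two-sided, with 0.005 as the smallest p that 400 relabellings allow). From control to unloading the interaction called 0 genes with edgeR, with 733 at an unadjusted p under 0.05 and 0 by DESeq2. The Schwann cell list differed by a median of -0.62 (adjusted p = 8.62e-09; adjusted p = 0.378 with an estimated correlation) with 0 of 11 called (0 adjusted over the list alone). Without the low-count filter that interaction called 122 genes.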

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

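The tests of scaling, of dilution, of a uniform response, of single libraries, of nerve content and of a wrong label, and the counts over other splits, were chosen or had their outcomes written down only after the results they bear on were seen. The interaction tests between the genotypes were planned, and the results in the next paragraph are those that differed between flox and mKO by such a test.

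From control to unloading 12 gene lists differed between the genotypes, from unloading to reloading 24 and from control to reloading 19. With an estimated correlation 0 of the 12, 2 of the 24 and 5 of the 19 passed, and fry called 0, 5 and 9. Without each single library 5, 16 and 13 passed at the preset correlation. From unloading to reloading the cytokine, chemokine and NF-kB list differed by a median of -0.52 and the cell cycle list by -1.15. The change from control to reloading differed in 93 genes. It was higher in mKO for Myh13 (1.38), a myosin heavy chain gene, Slc25a47 (0.87), Rilp (0.75) and Fastkd1 (0.6). It was lower for Nxpe5 (-4.33), Srp54b (-4.01, uncertain because close copies share its sequence), Cenpf (-3.73), Ccnb1 (-3.67), Ccl8 (-3.57) and Ncapg (-3.42). The lists differed by medians of -1.15 for macrophage and monocyte, -0.6 for antigen presentation, -0.5 for interferon response, -0.38 for cytokine and -1.72 for cell cycle.

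Cell cycle and macrophage lists were lower in mKO than flox at reloading. Scaling of the libraries was argued against, since with total counts the medians were -1.31 for macrophage and -1.63 for cell cycle while the median of all genes shifted by -0.134. A higher share of fibre RNA would lower every other cell type alike, but the macrophage list mean lay -0.96 ± 0.19 (SE) log2 below the endothelial one in mKO minus flox. A response from unloading to reloading smaller by 1 factor (0.74) stays open for the cell cycle and macrophage lists taken by themselves. It needed mKO minus flox differences of -0.35 for the macrophage list and -0.67 for the cell cycle list. Seen were -0.89 ± 0.31 (SE) and -1.25 ± 0.29, with gaps of -1.73 and -1.99 SE. The atrophy list gave -0.26 ± 0.09 where 0.08 was needed, a gap of -3.98 SE. Without Mt1 and Mt2 it gave -0.09 ± 0.08 against 0.13, a gap of -2.95 SE. The mean of all 20 atrophy members changed by -0.31 in flox and by -0.57 in mKO. Since 1 factor scales a list mean whichever way its members move, the atrophy values argue against 1 factor shared by every gene. The factor was taken as exact, so the gaps leave out its spread. The 10 members that fell in flox, chosen by that fall, gave 0.05 ± 0.15 against 0.22, a gap of -1.1 SE. A smaller number of macrophages and dividing cells, or less expression in each, may underlie the pattern, and these data do not separate them.

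The Schwann cell list was called lower in mKO than flox at unloading with the preset correlation, with 0 of 11 members called. It did not pass with an estimated correlation (adjusted p = 0.755) or with fry (adjusted p = 0.806). A single library was argued against as the source of the call at the preset correlation, since the highest adjusted p without 1 library was 0.00134. The group means of 0.46 in flox and -0.03 in mKO lay 1.67 pooled standard deviations apart, and mKO unloading replicate 2 (0.38) lay within the flox range of 0.37 to 0.58. Different amounts of nerve in single muscle samples may therefore account for it, and an effect of the genotype stays open as well.

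In mKO reloading, replicate 2 lay nearer to flox than replicates 1 and 3. A flox reloading library under an mKO label was argued against, since replicate 2 lay 2.42 flox standard deviations below the lowest flox library for the macrophage list and 5.27 below it for the cell cycle list. A difference between single animals or samples stays open and was not tested.

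In each comparison of 2 groups there were 10 splits of the 6 libraries, too few for a share under 0.05, and only the real values and the highest other splits are given. For 7 of these 9 comparisons 1 split, the real one, gave as many genes. The real and highest other counts in flox were 1024 and 0 for unloading against control, 5692 and 0 for reloading against unloading, and 4035 and 2 for reloading against control. In mKO they were 1382 and 1, 3270 and 0, and 389 and 0 in that order. Between genotypes they were 875 and 44 at reloading, and 0 and 0 at control and 0 and 1 at unloading, where 10 of 10 splits gave as many. With a real count of 0 every split must give as many, so those 10 of 10 test nothing. Where groups differ, a split that mixes them puts their difference into the spread within groups. Low counts in the other splits thus follow largely from the design. For the interactions 100 of 200 splits were drawn. The 93 genes of reloading against control were reached by 4 of 100 splits, the real one included, with 240 as the highest other. This share lay narrowly under 0.05, but the check was chosen after the result and drew only part of the splits. Chance is therefore not excluded. The count of 93 became 0 without flox reloading replicate 1. For the other 2 interactions, with 0 genes, every split must give as many, so the 100 of 100 that did test nothing. Their highest other counts were 2 for unloading against control and 357 for reloading against unloading. The 240 and 357 came from splits that kept the 6 reloading libraries grouped by genotype and mixed the control or unloading libraries, which points to the difference at reloading as a structure of the samples.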

How the results depend on the processing

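The tests named here were planned. Counts of changed genes were within 1.5 times of the reported value with RLE size factors in all 12 comparisons, and otherwise except as follows. With total counts they were 1485 for mKO against flox at reloading and 284 for the interaction from control to reloading. With no low-count filter they were 1651 for unloading against control in flox, 1216 for reloading against control in mKO, 148, 133 and 1557 for mKO against flox at control, unloading and reloading, and 122, 564 and 755 for the interactions from control to unloading, from unloading to reloading and from control to reloading. Of these calls 19, 13, 2, 5, 16, 2, 0 and 6 fell on genes outside the reported filter, and the cause was not tested. The stricter filter gave 158 for the last interaction. Modelling the compared groups alone gave 879, 2107 and 138 for unloading against control, reloading against unloading and reloading against control in mKO, and 443 for mKO against flox at reloading. DESeq2 gave 1538 for unloading against control in flox, 891 for reloading against control in mKO, 1387 for mKO against flox at reloading, and 142 and 422 for the interactions from unloading and from control to reloading.

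With a replicate block the last 2 interactions called 10 and 143 genes. The replicate numbers were not taken as pairs, since the labels name no shared source and 2 of 45 pairs with the same number had residuals that correlated across genes at over 0.1. The median was 0.024 over these 45 pairs, against -0.004 over 90 pairs with different numbers. Of 18 libraries 11 correlated best with their own number, where 6 are expected. In a check chosen after the result was seen, 448 of 7776 relabellings reached 11, so a weak shared source stays open.

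Without 1 library each, the counts ran from 364 to 801 for unloading against control in flox, 4241 to 5136 for reloading against unloading and 2758 to 3642 for reloading against control. In mKO they ran from 508 to 1466, 2058 to 3245 and 85 to 394 in that order. For mKO against flox they were 0 at control, 0 at unloading and 127 to 1630 at reloading, and for the interactions 0 from control to unloading, 0 to 98 from unloading to reloading and 0 to 448 from control to reloading. The cause of the lower and the higher counts was not tested.

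The difference in response size ran from -0.167 to -0.083 for reloading against unloading and from -0.01 to 0.078 for unloading against control, where it changed sign without flox control replicate 3 (-0.007) and without flox unloading replicate 2 (-0.01). The slow fibre list in mKO against flox at unloading turned without flox unloading replicate 1 (0.05, range up to 0.74). In reloading against control in mKO the oxidative phosphorylation list (0.05, range from -0.14) and the TCA cycle list (0.04, range from -0.21) turned without mKO reloading replicate 2. Zfp697 in mKO against flox, which passed in no setting, turned at unloading with total counts (-0.02), with a replicate block (0), and without flox unloading replicates 1 (-0.02) and 3 (0) and mKO unloading replicate 1 (-0.39), with 0.23 as the highest. At control it turned without flox control replicates 1 (-0.1) and 2 (-0.11) and mKO control replicates 2 (-0.05) and 3 (-0.02), with 0.28 as the highest. In reloading against unloading in mKO it turned without mKO unloading replicates 2 (-0.2) and 3 (-0.09) and mKO reloading replicate 2 (-0.11), with 0.42 as the highest. Of 188 list calls 20 held with an estimated correlation and 100 with fry.

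Of 32258 genes with a count 17833 passed the low-count filter and were tested, so at this depth nothing is said of the others. Whether depth limited calls among the tested genes was not examined.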

Other observations

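The values in this part are planned tests and no hypothesis is added. Several further gene lists moved with reloading. Circadian clock genes fell from unloading to reloading in flox with a median of -0.56 (adjusted p = 0.0234; adjusted p = 0.235 with an estimated correlation). Of 15 genes 9 fell (11 down and 2 up adjusted over the list alone), among them Ciart at -1.39 ± 0.33 and Cry2, a repressor of the clock, at -0.83 ± 0.21. Without flox reloading replicate 1 the adjusted p was 0.0546. In mKO the same list gave -0.2 (adjusted p = 0.0831), where Per1 fell by 1.55 ± 0.27 on the log2 scale. The lysosome list had a median of 0.23 in flox (adjusted p = 0.000547; adjusted p = 0.289 with an estimated correlation). Of 20 genes 8 rose (8 up and 1 down adjusted over the list alone), with Gusb at 1.43 ± 0.13. The complement list had a median of 0.83 (adjusted p = 0.00368; adjusted p = 0.351 with an estimated correlation). Of 13 genes 7 rose (7 adjusted over the list alone), with C1qb at 1.57 ± 0.19. C1qa, C1qb and C1qc are also on the macrophage and monocyte list, so these lists are not separate observations. The cytosolic ribosome list was higher in flox reloading than control by a median of 0.16 (adjusted p = 0.000296; adjusted p = 0.456 with an estimated correlation). Of 46 genes 11 were higher (13 adjusted over the list alone), with Rpl3 at 1.12 ± 0.12. The mitochondrially encoded list had a median of -0.51 there (adjusted p = 5.87e-05; adjusted p = 0.238 with an estimated correlation). Of 13 genes 7 were lower (8 adjusted over the list alone), with mt-Nd2 at -0.68 ± 0.11. Mitochondrially encoded genes took 8.43 ± 0.15% of counts (SD, n = 3) against 11.3 ± 0.84% at control.

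In mKO muscle from unloading to reloading the red blood cell list rose by a median of 1.15 (adjusted p = 0.00786; adjusted p = 0.507 with an estimated correlation). Of 7 genes 4 rose (6 adjusted over the list alone), with Hba-a1 at 1.17 ± 0.26, which is uncertain because its copies share sequence. The adipocyte list fell with a median of -0.72 (adjusted p = 0.0142; adjusted p = 0.609 with an estimated correlation). Of 12 genes 4 fell and 1 rose (7 and 1 adjusted over the list alone). The call was lost without mKO unloading replicate 2 (adjusted p = 0.111) and without mKO reloading replicate 3 (adjusted p = 0.0789). The proteasome list fell with a median of -0.1 (adjusted p = 0.0272; adjusted p = 0.66 with an estimated correlation). Of 31 genes 6 fell (6 adjusted over the list alone). The call was lost without mKO unloading replicates 1 (adjusted p = 0.0681) and 3 (adjusted p = 0.0621), without mKO reloading replicate 3 (adjusted p = 0.107) and with total counts (adjusted p = 0.0539). Psmd1 fell by 0.31 ± 0.06 on the log2 scale. The slow fibre list rose in flox from unloading to reloading by a median of 0.45 (adjusted p = 0.0299; adjusted p = 0.58 with an estimated correlation). Of 12 genes 2 rose (1 adjusted over the list alone). The call was lost without flox unloading replicate 1 (adjusted p = 0.159) and without flox reloading replicate 2 (adjusted p = 0.0804). The calcium store gene Casq2 rose by 2.13 ± 0.27. Lists of T and NK cell, B cell, smooth muscle and pericyte, and skin and hair markers were called in none of the 12 comparisons, with lowest adjusted p of 0.125, 0.255, 0.293 and 0.0842. Only 8 of 17 T and NK cell markers and 3 of 10 skin and hair markers passed the low-count filter, so little is said of those 2 lists.

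The authors' 4 deposited DESeq2 tables held 30881 genes each. Their p-values matched an own DESeq2 fit across genes, which are not independent replicates. On the log10 scale they correlated at 1 with mKO against flox at control, and at 0.998, 0.999 and 0.999 with the interactions from control to unloading, from control to reloading and from unloading to reloading. The log2 fold changes had the same sign in 90% of genes for the control table, and in 94%, 93.7% and 93.5% for those interactions. The 3 tables named by condition thus matched the mKO minus flox difference of each change. A negative value there means a lower change in mKO, not a fall at reloading. The table named reloading against control called 427 genes, 92 up and 335 down, of which 419 were also called in the own interaction fit of 422. The table named reloading against unloading called 145 genes, 16 up and 129 down, of which 142 were shared, and the other tables called 0, with 824 and 855 genes at an unadjusted p under 0.05. Among the smallest adjusted p were the mitotic genes Anln (-1.47, adjusted p = 1.01e-06) and Tpx2 (-1.88, adjusted p = 1.03e-06) in the table named reloading against control.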
